A study of Mus musculus with 7 samples.

How the data were processed

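RNA-seq was measured in 7 mouse libraries. Per the labels' protocols, 50000 iKPC cells were embedded in 500 µL Matrigel and cultured for 72 h with dox, the gels were washed, and medium with or without dox was given for 48 h before recovery with Dispase II at 100 µg/mL, RNA isolation with a Qiagen kit and paired-end sequencing by BGI. The same protocol text is attached to the CAF library, but it speaks of iKPC cells, and that library's tissue label also reads as cancer cells while its cell type label says fibroblast. Whether the CAF library was grown in the same way is therefore open.

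The deposited values are TPM per gene and library, per the file headers. The build was mm10, per the submitters' processing notes, and the aligner, quantifier and annotation are not given in the sources used here. TPM keeps no read depth, so no counting error could be attached to a value and low values are less certain than their decimals show. A rise of abundant genes lowers all others on this scale. The table held 0 mitochondrially encoded genes and none of the 11 markers of RNA quality fixed beforehand, so that list gave no result. An exact 0 is reported as listed at 0.

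Of 18735 gene IDs, 18609 matched the RefSeq table of GRCm38.p6, the assembly that mm10 corresponds to, from which coordinates were taken. A spreadsheet had turned 25 symbols into dates, and all 25 were restored through the gene ID. There were 18408 protein-coding genes, and 0 value columns were without a sample.

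Groups came from the sample titles: iKPC on dox (3 libraries), iKPC off dox (3) and CAF (1). The replicate numbers are the cell lines, so on and off libraries of 1 number come from the same line. The correlation of deviations from the group means across genes was 0.789, 0.801 and 0.809 for the same line. Values for different lines are pushed below 0 by the centring and say nothing more. Whether the lines came from separate animals is not given in the sources used here. Without the cell line as a block, the p-values measure the spread between the lines within each condition. With it, they measure the spread of the off minus on change between the lines.

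Genes with a mean of at least 1 TPM over the 6 iKPC libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend), off minus on dox, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels name no test, so the fit without a block was set as the main one before the data were examined, and the fit with the cell line as a block (the blocked fit) as its alternative. Fold changes on the log2(TPM + 1) scale understate the change of low genes. Lists were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives, adjusted over 38 lists with at least 3 tested members out of 41 fixed before the data were examined. The list of stellate and mesenchymal transcription factors had 2 tested members and that of endothelium 1, so neither was tested as a list. Fry asks whether a list moves one way and does not compare it with other genes.

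The CAF library was compared with the mean of the 3 iKPC off libraries without a test, over genes with a mean of at least 1 TPM in these 4 libraries. A difference of 4-fold with all 3 off libraries on one side was counted. List medians were placed among 10000 random lists matched in 20 bins of mean expression, in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6.

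Named genes followed a rule set before the data were examined: Kras and the ERBB genes, up to 4 members of each list with the largest change among those called (in the blocked fit where the unblocked one called none), the 12 largest rises and 12 largest falls among genes called in the unblocked fit with a mean of at least 5 TPM and the same direction in 3 lines, and for the CAF library the 10 largest differences each way at 20 TPM or more on the higher side, with the members of the fibroblast, CAF, epithelial and ERBB lists. Predicted genes were counted and not named. Cd14, Ptprc, Lyz2, Ifne, Sprr1a, Sprr2h and Hmgcs2 were named after their values were seen.

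Both fits were tested on simulated data for the off against on comparison, made from the real means and line levels, with 11525 genes passing the filter. The noise had the residual spread of the blocked fit, so that fit was favoured by construction. Far fewer genes were changed than the blocked fit called in the real data, so the recovered shares do not carry over to it. The unblocked fit recovered 3% of 100 genes changed by 1 on the log2 scale and 57% of 100 changed by 2, with 0 false calls, and the blocked fit 57% and 85% with 1 false call. Alternatives were other pseudocounts, filters, scalings and variance settings, leaving out each library or line, and the blocked fit.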

Results

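RNA was sequenced from 3 mouse pancreatic ductal adenocarcinoma lines, called iKPC lines 1 to 3, in which oncogenic Kras is expressed while doxycycline (dox) is in the medium. Each line gave 1 library kept on dox and 1 library without dox for 48 h, all grown in 3-D Matrigel, and 1 further library came from a line of cancer-associated fibroblasts (CAF) also labelled off dox. The 7 libraries were available as TPM (transcript abundance scaled to a common total) for 18735 genes, with no read counts, so the depth of each library is unknown. Between 13719 genes in the CAF library and 14813 genes in the off library of line 2 were listed above 0. The 10 most abundant genes took from 10.6% of TPM in the CAF library to 18.1% in the on library of line 1, where Sprr1a, a cornified envelope gene, led at 36932 TPM.

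The first comparison asked what changed in the cancer cells once dox was withdrawn and the Kras transgene was thereby switched off. Dox and the transgene changed together in each pair, so no change below separates an effect of dox itself. Kras itself (gene ID 16653, chromosome 6, 145216699 to 145250420 in GRCm38) fell in all 3 lines, from 74.8, 44.4 and 79.4 TPM on dox to 8.65, 11.8 and 12.9 TPM off dox. The means were 66.2 ± 19.0 and 11.1 ± 2.18 TPM (SD, n = 3 each), and the change was −2.45 on the log2(TPM + 1) scale (SE 0.27, limma adjusted p = 0.0185). These values pool the transgene with the endogenous gene. The call held without the on library of line 2 and was lost when any other single library was left out, with adjusted p between 0.068 and 0.0792, while with the cell line as a block the adjusted p was 9.33e-06.

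**Figure D1:**
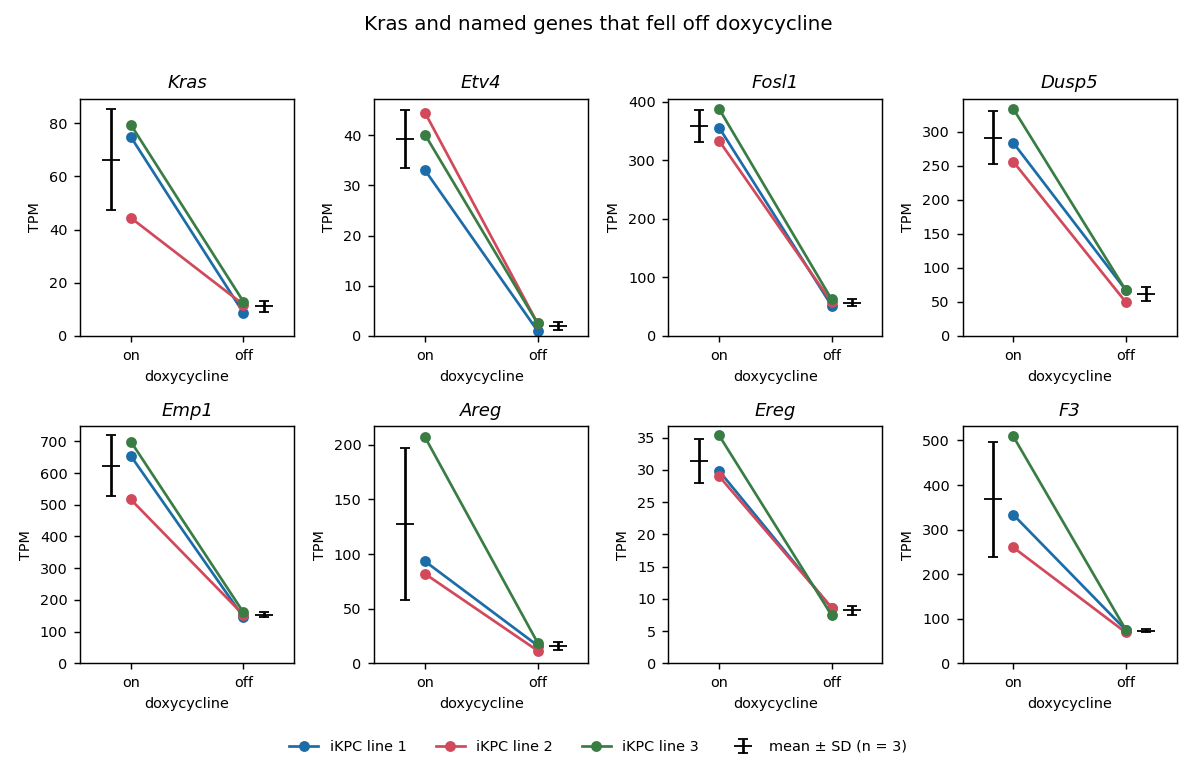
TPM (linear axes from 0) of Kras and 7 named genes that fell, in the on and off dox libraries of the 3 iKPC lines. Coloured points joined by a line are 1 cell line and black bars are mean ± SD (n = 3). Kras lies at 44.4 TPM or more on dox and at 12.9 TPM or less off dox.

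The 12 named genes that fell had the largest falls among genes called in the unblocked fit. Sprr2h, a cornified envelope gene, fell further but was called only with the block (−3.83, from 530.9 to 35.4 TPM, limma adjusted p = 0.0820, blocked 1.81e-07). Other genes called only with the block also fell further than some of the 12. Etv4, an ETS transcription factor induced by ERK signalling, fell from 39.2 ± 5.79 to 2.00 ± 0.863 TPM (log2 change −3.78, SE 0.27, limma adjusted p = 0.00921), and Fosl1, an AP-1 subunit, fell from 359 ± 27.4 to 56.9 ± 5.43 TPM (−2.64, SE 0.15, limma adjusted p = 0.00468). Dusp5, a nuclear ERK phosphatase, fell from 291 to 61.2 TPM, and F3, which encodes tissue factor, from 368 to 73.0 TPM. Ivl, the cornified envelope protein involucrin, fell from 857 to 74.7 TPM, the cytokine gene Il1a from 80.5 to 6.92 TPM and Angptl4, an inhibitor of lipoprotein lipase, from 225 to 38.9 TPM. Areg, Sprr2f, Pbp2 and Nav3 completed the set with Kras, at log2 changes of −2.85, −2.35, −2.25 and −2.22. Sprr2f and Sprr2h belong to a family of near-identical genes among which reads may have been split.

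The 12 named genes that rose were likewise the largest rises among genes called in the unblocked fit. Hmgcs2, at 2.98, was larger than most of them but called only with the block, and it was not the only such gene. Abcg5 and Abcg8, whose products form a sterol exporter, rose from 1.39 ± 0.783 to 18.04 ± 6.31 TPM and from 0.933 ± 0.494 to 14.2 ± 0.841 TPM, with log2 changes of 3.00 each (SE 0.33 and 0.24). Csf1, the growth factor of macrophages, rose from 22.1 ± 3.26 to 136 ± 21.7 TPM (log2 change 2.56, SE 0.19, limma adjusted p = 0.00921), and the bacterial lipoprotein receptor gene Tlr2 from 3.65 to 30.8 TPM. Pigr, which carries polymeric immunoglobulin across epithelium, rose from 16.4 to 92.4 TPM, and the fatty acid binding protein gene Fabp3 from 17.2 to 94.5 TPM. Clec2h, Dio1, Cyp2c55, Nlrp6, Ms4a18 and Nkain4 rose by 3.14, 2.49, 2.39, 2.37, 2.26 and 2.09 on the log2 scale. Clec2h and Cyp2c55 have close paralogs, so their values are uncertain in the same way as that of Sprr2f.

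Of 11589 genes tested, 263 passed an adjusted p of 0.05 in limma, with 157 higher and 106 lower off dox, and 222 of them changed at least 2-fold. With the cell line as a block 4670 genes passed, 3024 higher and 1646 lower, which included all of the 263, and 878 of these changed at least 2-fold. All 263 moved in the same direction in the 3 lines, which being called in these lines itself favours. Of the genes tested 65.6% did so, where 25% would if directions were independent and evenly split. The median change was above 0 in each line (0.047, 0.094 and 0.195), so 25% is not an exact reference. The median gene moved by 0.12 on the log2 scale, and by 0.0077 after quantile normalization. That normalization gave 133 genes higher and 203 lower, and median-of-ratios scaling 119 higher and 192 lower, so without the block the majority direction turned with the scale. In the blocked fit with median-of-ratios scaling 2334 were higher and 2212 lower. Without the filter on low TPM 109 genes passed and 19 named genes lost their call, with adjusted p from 0.0567 for Dio1 and Parp9 to 0.0908 for Fabp3. Without the on library of lines 1, 2 and 3 the unblocked fit called 0, 22 and 0 genes, and without their off library 2, 8 and 11, against 1906 to 2160 genes at an unadjusted p under 0.05.

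Of 3 genes for ERBB receptors tested none passed over all genes and 1, Erbb2, was higher when adjusted over the list alone; in the blocked fit 2 rose. Erbb2 was at 64.2 ± 2.23 TPM on dox and 99.5 ± 4.14 off dox (log2 change 0.62, limma adjusted p = 0.0628, blocked 0.000755), and Erbb3, the receptor that binds neuregulins, at 39.2 ± 9.31 and 56.6 ± 8.36 (0.53, limma adjusted p = 0.206, blocked 0.00383). Egfr was at 34.9 ± 5.01 and 40.1 ± 10.1 TPM with no call in either fit, and Erbb4 was listed at 0 in all 6 libraries. As a list the receptors did not pass limma's camera (adjusted p = 0.186).

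Among 7 ERBB ligand genes tested, 3 fell over all genes, 4 when adjusted over the list alone and 6 in the blocked fit. Areg, an EGFR ligand, fell from 128 ± 69.2 to 15.6 ± 3.70 TPM (limma adjusted p = 0.0242), Ereg from 31.4 ± 3.44 to 8.21 ± 0.666 TPM (0.0169) and Btc from 67.4 ± 12.4 to 26.7 ± 4.75 TPM (0.0348). Nrg1, the neuregulin named in the series title, was at 6.53 ± 2.61 TPM on dox and 2.95 ± 1.15 off dox (log2 change −0.91, limma adjusted p = 0.198, blocked 0.00207). Tgfa, at −0.89, passed adjusted over the list alone and in the blocked fit (adjusted p = 0.000219), and Hbegf, at −0.70, in the blocked fit (adjusted p = 0.000538). Nrg4 was at 1.39 and 1.64 TPM without a call. The ligand list passed limma's camera (adjusted p = 4.92e-06) with a preset correlation, and had an adjusted p = 0.271 with an estimated correlation.

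**Figure D2:**
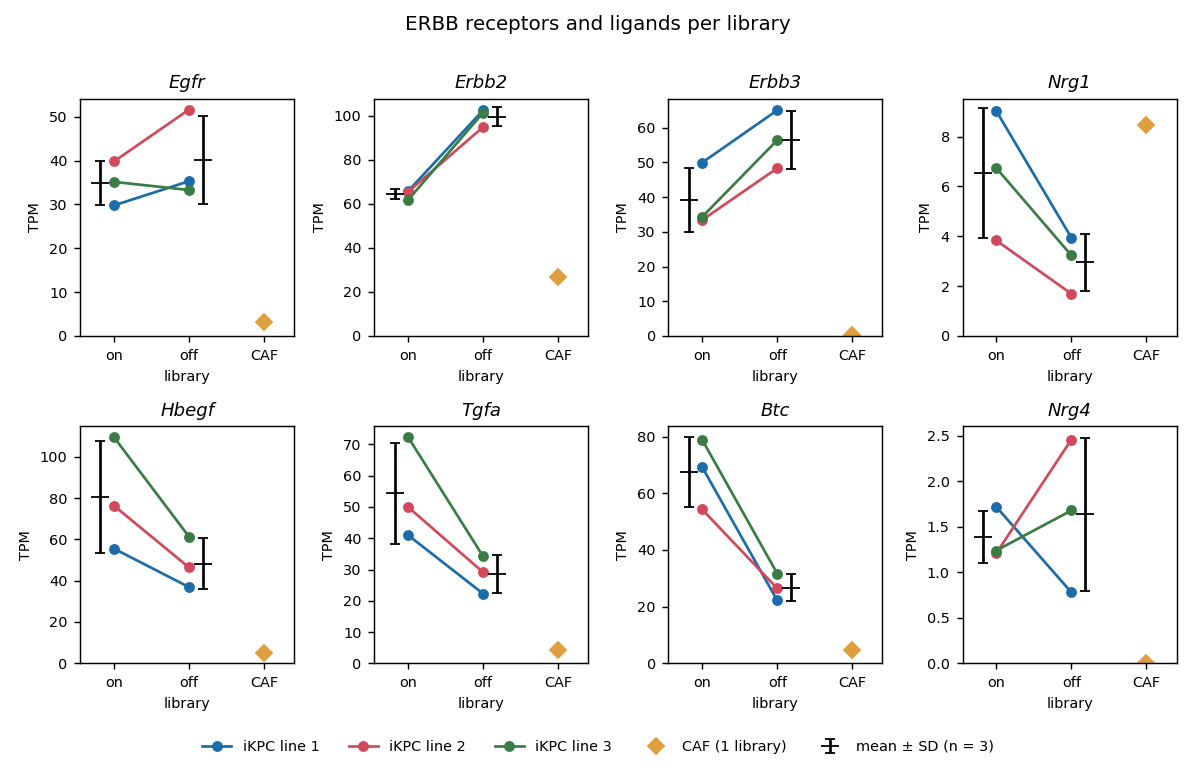
TPM (linear axes from 0) of ERBB receptor and ligand genes in the on and off dox libraries of the 3 iKPC lines and in the CAF library. Coloured points joined by a line are 1 line, black bars are mean ± SD (n = 3) and the diamond is the single CAF library. Erbb2 is higher off dox in the 3 lines, and Nrg1 stands at 8.45 TPM in the CAF library against 2.95 TPM on average in the off libraries.

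Lists of genes fixed beforehand showed where further changes lay. Of 38 lists with at least 3 tested members, 11 passed limma's camera with a preset correlation of 0.01 and 13 did in the blocked fit. None passed when the correlation was estimated, the smallest adjusted p being 0.270 and, in the blocked fit, 0.436. With an estimated correlation camera has only the few residual degrees of freedom that 6 libraries leave, so it could hardly call a list. The MHC class I list had an estimated correlation of −0.046, under the preset one, and still a camera adjusted p = 0.270. These values therefore do not tell whether correlation between genes accounts for the list calls. The 9 other ways of splitting the same 6 libraries gave 6 to 15 lists by the same test. Each of these splits still had unequal numbers of on and off libraries in its groups, so part of the dox change remained in it. They are thus no dox-free reference, and the count of 11 lists by itself does not set the dox split apart.

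Of 19 MAPK output genes tested, 8 fell over all genes, 10 when adjusted over the list alone and 16 in the blocked fit, with a list median of −0.89 (camera adjusted p = 3.53e-13, and adjusted p = 0.270 with an estimated correlation). Besides Etv4, Fosl1 and Dusp5, Emp1, an epithelial membrane protein gene, fell from 623 ± 95.2 to 153 ± 7.63 TPM. Rin1, a RAS effector in the list of macropinocytosis and RAS effectors, fell from 42.03 to 17.75 TPM.

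Genes of proliferation and ribosome production were lower off dox. Of 30 G2/M genes 2 fell over all genes, 23 adjusted over the list alone and 28 in the blocked fit (median −0.97, camera adjusted p = 1.18e-17, adjusted p = 0.447 with an estimated correlation). Ccna2, cyclin A2, fell from 28.8 to 9.52 TPM and Kif23, a kinesin of cytokinesis, from 51.3 to 29.0 TPM. Of 29 G1/S genes 2 fell, 5 adjusted over the list alone and 22 in the blocked fit (median −0.70, camera adjusted p = 7.03e-13, adjusted p = 0.442 with an estimated correlation), among them Uhrf1, from 21.2 to 5.80 TPM, and Rrm2, a ribonucleotide reductase subunit, from 71.4 to 23.6 TPM. Of 30 MYC and ribosome biogenesis genes 3 fell, 25 adjusted over the list alone and 29 in the blocked fit (median −0.73, camera adjusted p = 1.03e-17, adjusted p = 0.411 with an estimated correlation). Odc1, which starts polyamine synthesis, fell from 156 to 64.7 TPM, Pa2g4 from 228 to 130 TPM and Dkc1, the pseudouridine synthase dyskerin, from 25.5 to 10.1 TPM.

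Of 23 cholesterol biosynthesis genes 9 fell over all genes, 17 adjusted over the list alone and 19 in the blocked fit (median −1.04, camera adjusted p = 9.89e-16, adjusted p = 0.270 with an estimated correlation). Pcsk9, which directs the LDL receptor to degradation, fell from 22.7 to 4.92 TPM, Idi1 from 37.5 to 9.35 TPM, Cyp51 from 83.4 to 24.6 TPM and Ldlr, the LDL receptor gene, from 61.2 to 18.5 TPM. Of 23 ATF4 and amino acid stress genes none passed over all genes, 1 was higher and 8 lower adjusted over the list alone, and 4 rose and 14 fell in the blocked fit (median −0.41, camera adjusted p = 0.000113, adjusted p = 0.598 with an estimated correlation). In the blocked fit the serine synthesis genes Phgdh and Psat1 fell by 1.72 and 1.83 on the log2 scale, and Mthfd2, of mitochondrial folate metabolism, fell by 1.33.

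Antigen presentation, interferon-responsive and lysosomal genes were higher off dox. Of 26 interferon response genes 3 rose over all genes, 8 adjusted over the list alone and 19 in the blocked fit (median 0.91, camera adjusted p = 4.09e-05, adjusted p = 0.598 with an estimated correlation). Irf1, an interferon regulatory factor, rose from 44.2 ± 3.98 to 138 ± 19.5 TPM, and Parp14 and Parp9 rose from 1.75 to 7.94 TPM and from 11.7 to 31.5 TPM. Of 10 MHC class I presentation genes 1 rose, 8 adjusted over the list alone and 10 in the blocked fit (median 1.03, camera adjusted p = 6.81e-05, adjusted p = 0.270 with an estimated correlation). Tapbp, which loads peptides on MHC class I, rose from 146 to 348 TPM, with limma adjusted p = 0.0420 as deposited, 0.0641 after median-of-ratios scaling and 0.0515 after quantile normalization. Of 34 lysosome and autophagy genes 1, Lamp2, rose over all genes, 11 adjusted over the list alone and 25 in the blocked fit, where 1 fell (median 0.57, camera adjusted p = 5.82e-05, adjusted p = 0.270 with an estimated correlation). Lamp2 went from 261 to 496 TPM with limma adjusted p = 0.0494, and 0.0539 after median-of-ratios scaling. The summed TPM of the 17 leukocyte genes measured was higher off dox in all 3 lines, by 98.1, 46.2 and 48.4 TPM, mostly through Cd68, Cd14 and Laptm5, whereas Ptprc, the pan-leukocyte CD45 gene, was at 0.693 TPM on average on dox and 0.463 off dox, and Lyz2, a myeloid lysozyme gene, at 0.540 and 0.

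**Figure D3:**
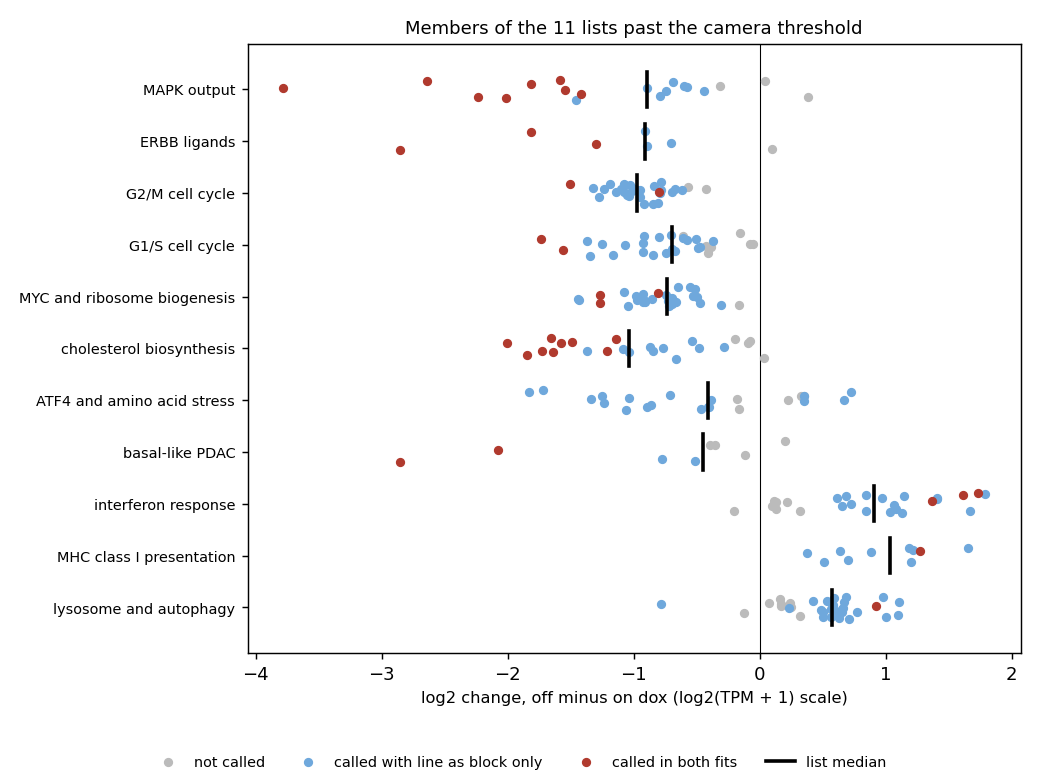
Log2 change off minus on dox, on the log2(TPM + 1) scale, for each tested member of the 11 lists that passed camera with a preset correlation. Each point is 1 gene, red if called in both fits, blue if called only with the cell line as a block and grey otherwise, and the black bar is the list median. Medians run from −1.04 for cholesterol biosynthesis to 1.03 for MHC class I presentation.

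Markers of tumour subtype were mixed. Of 8 basal-like genes 2 fell over all genes, 3 adjusted over the list alone and 4 in the blocked fit (median −0.45, camera adjusted p = 0.000749, adjusted p = 0.275 with an estimated correlation). These included Krt6a, a stress keratin, from 5.67 to 0.587 TPM, and Areg, which is also counted as a ligand. Of 20 classical genes none passed over all genes or adjusted over the list alone, and 12 rose and 3 fell in the blocked fit (camera adjusted p = 0.275). In that fit Cdx2, an intestinal transcription factor, rose from 72.9 to 210 TPM, Muc13 from 341 to 884 TPM and Spink4 from 12.2 to 54.6 TPM, while the gastric mucin gene Muc5ac fell from 53.2 to 20.9 TPM. Of 25 epithelial and duct genes none passed over all genes, 1 was lower adjusted over the list alone, and 10 rose and 6 fell in the blocked fit (camera adjusted p = 0.824), with Krt7 falling from 5596 to 2133 TPM and Muc1 rising from 2671 to 4866 TPM. Of 15 EMT and mesenchymal genes none passed over all genes, 1 was lower adjusted over the list alone, and 2 rose and 5 fell in the blocked fit, where the list passed camera (adjusted p = 0.0204, against 0.0577 without the block, and adjusted p = 0.436 with an estimated correlation in the blocked fit). The intermediate filament gene Vim fell from 989 to 375 TPM in that fit.

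The second comparison set the CAF library against the 3 iKPC libraries off dox. As there was 1 CAF library, the difference has no replicate check and no test was made. Of 12136 genes compared, 2488 lay at least 4-fold apart with all 3 iKPC off libraries on one side, 1062 higher and 1426 lower in the CAF library. Among the 10 named genes on the higher side, the collagen gene Col3a1 stood at 1043 TPM and was listed at 0 in the iKPC off libraries, Sparc at 1208 against 1.57 ± 0.451 TPM (SD, n = 3), Dcn at 443 against 0.0167, Col1a1 at 493 against 0.340 and Lox, which cross-links collagen, at 635 against 0.0067 TPM. The chemokine gene Cxcl12 was at 877 TPM and Serpinf1, Slpi, Rhox5 and Iglon5 were at 949, 878, 709 and 404 TPM, each at 0.910 TPM or less on average in the iKPC off libraries. On the lower side Krt19, a duct keratin, was at 7.60 TPM against 8325 ± 2049, Krt8 at 2.90 against 5041 and Lgals2 at 3.76 against 8235 TPM. Ctse, Mcpt2, Clca1, Ucp2, Gsta1, Lypd8 and Prap1 were the other genes named there, at 0 to 5.35 TPM in the CAF library.

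Of 19 fibroblast genes compared 18 were at least 4-fold higher in the CAF library, with a median difference of 6.06 on the log2(TPM + 1) scale, which stood at percentile 100 of 10000 random lists matched on mean expression. Pdgfrb was at 197 TPM and Postn at 349 TPM, whereas Col1a2 stood at 0.45 TPM and Fap and Thy1 were listed at 0 in the CAF library. These were not among the genes compared, since a gene near 0 in the iKPC libraries passed the filter only if high in the CAF library; of all 24 fibroblast genes listed, 20 reached 1 TPM in the CAF library and 8 in the mean of the off libraries. Of 11 inflammatory CAF genes compared 8 were higher (median 4.33, percentile 100), such as the chemokine gene Ccl2 at 1584 against 20.1 TPM. Of 13 myofibroblastic CAF genes compared 8 were higher (median 2.33, percentile 99.99), such as Acta2, smooth muscle actin, at 86.2 against 1.57 TPM. The same filter acted on these lists. Of all 18 inflammatory genes measured, 14 reached 1 TPM in the CAF library and 8 in the mean of the off libraries. Of all 17 myofibroblastic genes measured, 14 and 8 did. Of 5 antigen-presenting CAF genes 2 were higher and 2 lower (median 1.04, percentile 92.1). Of 25 epithelial and duct genes 21 were lower and 2, Sox9 and Spp1, were higher (median −6.13, percentile 0), and of 20 classical genes 19 were lower (median −6.59, percentile 0). Of 22 EMT and mesenchymal genes 15 were higher (median 4.20, percentile 100). High percentiles were not limited to fibroblast lists. The G1/S, G2/M and MYC and ribosome biogenesis lists also stood at percentile 100 (medians 1.67, 2.25 and 1.03), and cholesterol biosynthesis at 99.92.

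Of the ERBB genes compared, 2 of 3 receptors and 3 of 7 ligands were at least 4-fold lower in the CAF library. Erbb3 was at 0.13 TPM in the CAF library against 56.6 ± 8.36 TPM in the iKPC off libraries (SD, n = 3), Egfr at 3.20 against 40.1 ± 10.1 and Erbb2 at 26.6 against 99.5 ± 4.14 TPM. Nrg1 was at 8.45 TPM in the CAF library, above the 3.94, 1.69 and 3.23 TPM of the off libraries and within the 9.03, 3.83 and 6.74 TPM of the on libraries, a difference of 1.30 from the off libraries on the log2(TPM + 1) scale, and of 0.77 with a pseudocount of 5. Hbegf, Tgfa and Btc were lower in the CAF library by 3.06, 2.49 and 2.27, and Ereg, at 8.93 against 8.21 TPM, was close to the off libraries. The median of the 7 ligands was −1.35 (percentile 1.13) and that of the 3 receptors −3.26 (percentile 3.27).

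**Figure D4:**
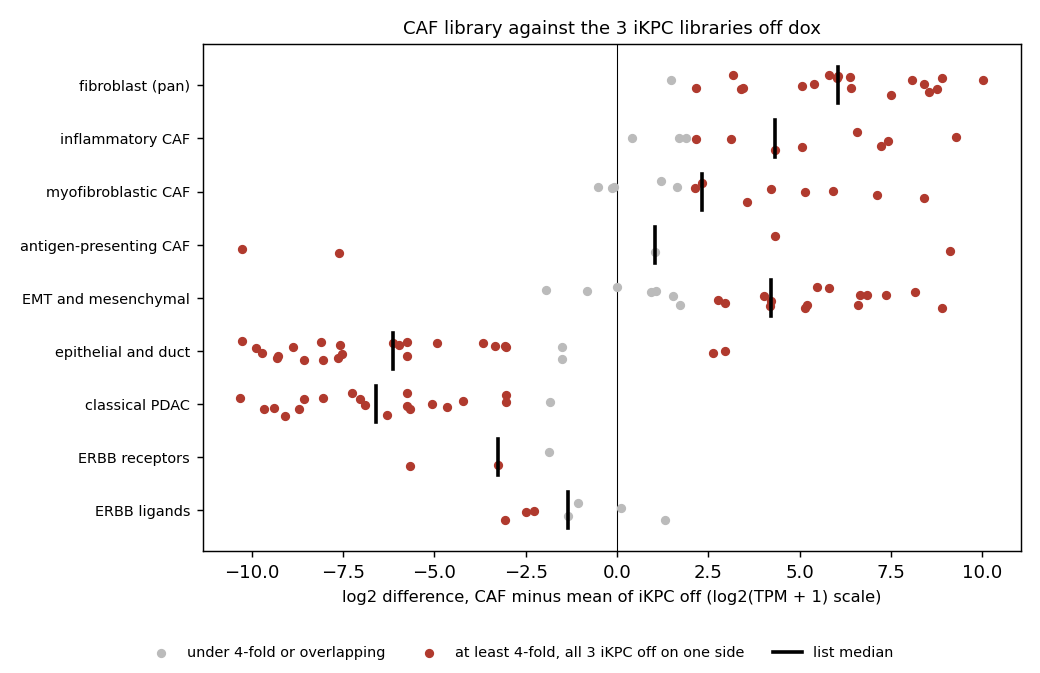
Difference between the CAF library and the mean of the 3 iKPC off libraries, on the log2(TPM + 1) scale, for members of 9 lists. Each point is 1 gene, red where at least 4-fold apart with all 3 off libraries on one side, and the black bar is the list median, from −6.59 for classical genes to 6.06 for fibroblast genes.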

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

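The lines moved in opposite directions for 6 named genes, and the difference between lines was not tested because each line has 1 library per condition. Egfr changed by −0.076 on the log2 scale in line 3, against rises in lines 1 and 2. Nrg4 changed by −0.61 in line 1, against rises in lines 2 and 3. Tnc changed by 0.021 in line 1 and was lower off dox in lines 2 and 3. Egfl7 changed by −0.35 in line 3. The Y-linked genes Kdm5d and Ddx3y changed by 0.53 in line 2 and by −0.48 in line 1, each against the opposite sign in another line. None of these genes was called without the block, and Tnc alone was called with it.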

How the results depend on the processing

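The tests with both added settings, the blocked fit with median-of-ratios scaling and with a pseudocount of 0.1, were chosen after the data were seen.

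With the cell line as a block, which takes out the level of each line, 4670 genes passed, 3024 higher and 1646 lower, against 263, 157 and 106 without it. The labels pair the libraries by line, so the unblocked error holds the differences between lines by construction. Blocking also added the EMT and the myofibroblastic CAF lists, ended no list call and strengthened 68 named genes. With median-of-ratios scaling the blocked fit gave 4546 genes (2334 higher, 2212 lower) and with a pseudocount of 0.1 it gave 4635 (3000 and 1635). In the blocked fit without line 1, 2 or 3, 4759, 3237 and 4176 genes passed, 3219, 2107 and 2476 of them higher and 1540, 1130 and 1700 lower, and 10 to 15 lists.

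In the unblocked fit, leaving out a library or line gave 0 to 22 genes, 0 to 9 higher and 0 to 13 lower, with fewer libraries to estimate the spread. Lists ranged from 12 to 14. Kras ranged from −2.76 to −2.18 and lost its call in all but 1 of these settings. Quantile normalization gave 203 genes lower and median-of-ratios scaling 192, as both move the median gene toward 0. Without the filter, where 16976 genes were tested, 109 passed, 60 higher and 49 lower. Why fewer passed was not tested. Camera with an estimated correlation, which has few residual degrees of freedom here, called 0 lists and fry 6, of which 5 were shared and ERBB receptors were added. In the blocked fit fry called 22 lists, 9 of them shared with unblocked camera. The other settings left the gene and list counts within 1.5 times.

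Some named genes near the threshold lost their call in 1 or more settings. Without the filter 19 did (Btc, Sesn1, Lamp2, Uhrf1, Ccna2, Kif23, Dkc1, Odc1, Idi1, Parp14, Parp9, Tapbp, Il1a, Birc3, Fabp3, Dio1, Ms4a18, Sprr2f and Nav3; adjusted p 0.0567 to 0.0908), as did the basal-like list. Without the trend 11 did, Pa2g4 among them (0.0517 to 0.0656), with a pseudocount of 0.1 5 did, Saa3 among them (0.0503 to 0.0631), and with 5 Dkc1 and Nav3 did (0.0503 and 0.0643). Lamp2, Tapbp and Ms4a18 did after quantile normalization (0.0525, 0.0515 and 0.0506), Lamp2 and Tapbp after median-of-ratios scaling (0.0539 and 0.0641) and Fabp3 with robust eBayes (0.0538).

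Some named genes turned sign, none of them called without the block. Leaving out a library or line, Egfr ranged from −0.016 to 0.30, Nrg4 from −0.18 to 0.45, Egfl7 from −0.031 to 0.35, Bnip3 from −0.080 to 1.48 and Laptm5 from −0.99 to 2.23. Kdm5d ranged from −0.79 to 1.21, Ddx3y from −1.33 to 1.09 and Col6a1 from −1.56 to 0.46. Some of these genes differed widely between lines. On dox in lines 1, 2 and 3, Laptm5 was at 43.4, 34.3 and 0.70 TPM and Col6a1 at 1.60, 0.91 and 18.6 TPM. Ddx3y was at 13.8 and 10.3 TPM in lines 1 and 2 and listed at 0 in line 3. For such genes, leaving a single library out of the unblocked fit shifts a group mean by the level of its line. In the blocked fit without line 1 Ddx3y was at 0.096, and without line 2 Nrg4 was at −0.18, Egfl7 at −0.031 and Kdm5d at −0.025. After quantile normalization Nrg4 was at −0.052 and Egfl7 at −0.054. For the other genes and settings the cause was not tested.

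For the CAF library a pseudocount of 5 gave 1395 genes, 499 higher and 896 lower, since it shrinks differences of low genes. Most single differences depend on the pseudocount: of 92 named genes 64 moved at 5 and 52 at 0.1, and 25 of 90 moved against all 6 iKPC libraries. Leaving out an iKPC off library gave 2461 to 2582 genes.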

Other observations

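Tests of common rescaling, admixed leukocytes and admixed cells in the CAF comparison were chosen after the results were seen, as were the tests of gene counts against other splits; those of LXR targets, interferon transcripts and list counts over splits were written down first. A first version of the leukocyte test, on 12 genes picked after their values were seen, gave a sum lower off dox in the 3 lines and was replaced by the full list fixed beforehand.

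Some metabolic and stress genes outside the lists that passed camera were called in the blocked fit. That fit called 4670 of all 11589 genes tested, 3024 higher and 1646 lower. None of the lists in this paragraph passed camera in either fit, so the counts do not set them apart from other genes. Of 19 glycolysis genes 6 rose and 4 fell (camera adjusted p = 0.882), with Gpi1 from 723 to 1171 TPM, and of 35 oxidative phosphorylation genes 10 rose and 1, Cycs, fell (0.308). Of 20 hypoxia genes 11 rose and 1 fell (0.607), of 22 immediate early genes 12 rose and 2 fell (0.0577), with Jun from 54.0 to 149 TPM and Egr3 from 20.8 to 6.31 TPM, and of 17 FOXO and receptor feedback genes 8 rose and 2 fell (0.321). Sesn1, a sestrin of that list, rose from 5.82 to 27.1 TPM without the block too. Of 15 KRAS-linked chemokines and cytokines 5 rose and 8 fell (0.158), Csf1 and Il1a standing at either end. Of 15 Wnt and stem genes 5 rose and 4 fell (0.607), with Aldh1a3 from 936 to 254 TPM and Aldh1a1 from 33.8 to 117 TPM, so these aldehyde dehydrogenases went opposite ways.

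The other lists gave smaller or mixed changes in the blocked fit, to be read against the 4670 of 11589 genes called in it. Receptor tyrosine kinases outside the ERBB family had 3 higher and 1 lower of 11 (camera adjusted p = 0.711), p53 targets 4 and 4 of 19 (0.568), endoplasmic reticulum chaperones 3 and 1 of 19 (0.860), apoptosis regulators 6 and 2 of 13 (0.426), macropinocytosis and RAS effectors 6 and 2 of 13 (0.718), YAP and TEAD targets 5 and 4 of 19 (0.568), acinar genes 1 and 1 of 3 (0.718), and pentose phosphate and hexosamine genes 0 and 1 of 13 (0.186). Fibroblast genes had 0 higher and 3 lower of 8 (0.356), myofibroblastic CAF genes 1 and 5 of 8 (0.0717, and 0.0106 with the block, where the adjusted p = 0.436 with an estimated correlation), inflammatory CAF genes 4 and 4 of 8 (0.962), antigen-presenting CAF genes 1 and 1 of 3 (0.630), leukocyte genes 3 and 1 of 6 (0.568), and nerve genes 1 and 0 of 3 (0.504). Y-linked genes had 0 and 0 of 4 (0.761). Reference genes had 3 higher and 2 lower of 12 (0.628), with Actb from 4298 to 3107 TPM. The camera direction was down while the median change was above 0 for the epithelial and duct, YAP and TEAD, p53, chaperone, inflammatory CAF, Y-linked and reference lists, and up with a median of −0.097 for antigen-presenting CAF genes. The stellate list had 1 lower of 2 tested, Twist2, and the 1 endothelial gene tested, Egfl7, was not called.

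The real split of the 6 libraries gave 263 genes, 157 higher and 106 lower, and the highest of the 9 others gave 0; 1 of 10 splits was as large. In the blocked fit the real split gave 4670 genes and the highest of the 3 others that part the pairs gave 0, so 1 of 4 was as large. With 10 and 4 splits the share is never under 0.05. For the lists, camera gave 11 in the real split and up to 15 in others, 6 of 10 splits being as large, and in the blocked fit 13 against up to 15, with 2 of 4 as large. Each other split still had unequal numbers of on and off libraries in its groups, so none was free of dox. Why these splits gave lists without giving genes was not tested.

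Of 23 cholesterol biosynthesis genes 9 were called lower off dox (19 in the blocked fit; camera adjusted p = 0.270 with an estimated correlation), while the sterol exporter genes Abcg5 and Abcg8 were higher. A common rescaling of TPM would shift all genes alike, yet the list median lay −1.07 from that of all genes on average over the 3 lines (SD 0.227). The list was taken up after camera, which compares a list with other genes, had called it, so this difference is no separate test. A candidate explanation is sterol excess sensed by LXR, which would raise its other targets. The median of 12 such genes was 0.37, above the 0.12 of all genes, but 3 were called higher and 2 lower in the blocked fit and none without the block, so this stays open. Dox and the transgene changed together in each pair, so an effect of dox itself was not separated.

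Of 26 interferon response and 10 MHC class I genes, 3 and 1 were called higher off dox (19 and 10 in the blocked fit; camera adjusted p = 0.598 and 0.270 with an estimated correlation). Their joint median lay 0.81 above that of all genes on average over the lines (SD 0.0925), which a common shift of all genes would not give. Both lists had already been called by camera with the preset correlation, which compares a list with other genes, so this is no separate test. Leukocytes in the off libraries may contribute: the summed TPM of the leukocyte list was 64.2 higher on average, but 3 members were called higher and 1, S100a9, lower in the blocked fit, and 9 of 17 were under 1 TPM in all 6 libraries. Ptprc (0.693 and 0.463 TPM) and Lyz2 (0.540 and 0 TPM) were lower off dox in each line, against admixture but near the floor, so this cannot be told apart from a change in the cancer cells. Of 6 interferon genes in the table the highest mean off dox was 2.29 TPM, for Ifne, which was lower off dox in line 3. Ifnb1 and the interferon lambda genes were not among the 6, so they could not be checked. An interferon source thus stays open as well.

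Nrg1 in the CAF library was at the level of the iKPC libraries on dox. By the largest share that any of 8 selected epithelial genes allows, admixed iKPC cells could supply 0.261% of the CAF level. By 7 selected fibroblast genes, admixed fibroblasts could supply 0.206% of the mean on level. These genes were part of a test chosen after the results were seen and were not the full lists. Fbln2, of the fibroblast list, was not among them. It was at 91.9 TPM in the on library of line 3 and 213 TPM in the CAF library, so its share would be far larger. Col3a1, which was among them, was at 0.17 TPM or less on dox and 1043 TPM in the CAF library. Both percentages from the selected genes are far below the level needed, so a hypothesis left open is that both cell types transcribe Nrg1. This hypothesis rests on that choice of genes and on 1 CAF library, and gene-level TPM does not separate Nrg1 isoforms.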
